A study of Mus musculus with 12 samples.

How the data were processed

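RNA-seq libraries of C2C12 cells on day 7 of differentiation were compared between an untreated group and a group given 25 µmol/L OI, with 3 libraries each. Per the labels' protocols, total RNA was extracted with RNAiso Plus and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, the tools were cutadapt 2.7, HISAT2 2.1.0 and StringTie 1.3.3b with the mouse genome build mm10. The authors deposited FPKM values, fragments scaled to gene length and library size, 1 table per sample, with each gene's identifier, symbol, biotype, position and length. The strand setting of the counting and the sequencing layout are not given in the sources used here.

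All 6 tables hold the same 27943 genes and annotation. The annotation of 1 row was broken and the row was left out, which left 27942 genes. Of these, 27793 have an identifier in GENCODE release M21 (GRCm38, the assembly also called mm10), and 27459 the same chromosome, start, end and strand there. Genes with identifiers between ENSMUSG00000000320 and ENSMUSG00000083778 were not analysed here, and neither was the second set of 3 control and 3 OI samples. The values per library differed between all replicates, so each library was counted as 1 sample.

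Depth was recovered from the FPKM values. In genes of 1 exon, FPKM times gene length fell on whole multiples of 1 step per library, and 100% of these values were within 0.01 of a whole number. The step gives library sizes from 24441000 to 36274000 to the nearest 1000, in reads or fragments, which the values do not tell apart. Over all genes above 0, between 84.5% and 86.0% of the values were whole with the deposited gene length. Outside genes of 1 exon it was between 64.6% and 66.4%, so recovered read numbers of such genes are approximate. The genes analysed took 23.9% of the reads in control replicate 1 and 5.25% to 5.77% in the others.

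Genes were tested where FPKM was 1 or more in at least 3 of the 6 libraries (1737 genes, 310 of them protein-coding, 393 processed pseudogenes, 334 antisense and 206 long intergenic RNAs). The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with trend=TRUE and no replicate block, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The fit was tested on simulated data with 200 changed genes among 1737: of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale it recovered 0, 25, 44 and 50, and it called 2 of the 1537 unchanged genes. Simulated values were drawn independently per gene and library, with no outlying library and no genes that share reads. These counts are therefore not the error rate of the real comparison.

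Named genes followed a rule: 19 sentinels, up to 3 members per fixed list past the threshold, and up to 8 rises and 8 falls past the threshold with no overlap between groups and a mean of 10 FPKM or more in the higher group, leaving out predicted models, which the rule defined as symbols made of Gm and a number, or holding Rik, LOC or -ps. It gave 8 genes. The 30 fixed lists hold 656 distinct genes, of which 9 were among the genes analysed and 7 were tested. Because no list had 3 tested genes, each tested gene was linked to list members after the data were seen. Exonic overlaps were taken from GENCODE M21 on either strand. Near-identical matches came from BLAST+ 2.17.0 (megablast, E-value at most 1e-10, at least 90% identity over at least 80% of the transcript) against protein-coding transcripts of other genes, best match only. Of the tested genes 908 shared exonic bases with another annotated gene and 515 had such a match. Linked lists with 3 or more genes were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over 15 lists), with an estimated correlation, and with fry. The union of the 6 muscle lists (myogenic transcription factors, sarcomere proteins, myoblast fusion, excitation-contraction coupling, neuromuscular junction and dystrophin complex, and muscle energy enzymes) was 1 of the 15, since none of the 6 had 3 linked genes.

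The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to a common sum, trend=FALSE, robust=TRUE, array weights, the replicate number as a block, and leaving out each library. The common sum was taken over the genes analysed only, so the rescaled values are not TPM over all genes. A limma voom fit on read numbers recovered from FPKM, for genes with 10 or more reads in at least 3 libraries, a fit on genes without any link, and a camera test of the linked lists with 1 value per list member, the mean over its linked genes, were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. Read-based intervals are not given, since groups were compared across replicates.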

Results

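RNA was sequenced from C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is reduced. The cells were grown to 80% density in medium with 10% fetal bovine serum and then kept for 7 days in 2% horse serum, either untreated (control) or with 25 µmol/L 4-octyl itaconate (OI), a cell-permeable derivative of the metabolite itaconate that is known to activate the transcription factor NRF2. The title of the series says that OI represses myogenic differentiation, and the comparison asks how the transcriptome differs with and without it. Each group had 3 libraries. The labels do not say whether the 3 came from separate cultures, so p-values measure the spread between these libraries, which may be technical. A further 3 control and 3 OI samples of the series were not analysed here. The analysis covered 27942 genes, mainly long non-coding RNAs, antisense RNAs, pseudogenes and recently annotated protein-coding genes. Most long-known muscle and stress genes carry Ensembl identifiers in a range between ENSMUSG00000000320 and ENSMUSG00000083778, which was not analysed here. That range holds 25827 genes of the reference annotation, 19521 of them protein-coding, so none of the 19 sentinel genes fixed beforehand, such as Myog or Nqo1, has a value. Library sizes recovered from the FPKM values, to the nearest 1000, were 24441000, 30522000 and 29993000 reads or fragments for control replicates 1 to 3, and 32122000, 36274000 and 25684000 for OI replicates 1 to 3.

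Control replicate 1 stood apart in abundant non-coding RNAs. AY036118, an rRNA-derived locus on chromosome 17, was at 70761 FPKM in that library and between 691 and 2450 FPKM in the other 5. The 7SL RNA gene Rn7s1 was at 480 FPKM there and between 8.11 and 11.8 FPKM elsewhere. Malat1, a nuclear long non-coding RNA, was at 1769 FPKM against 312 to 429 FPKM. The histone gene Hist2h3c1 was at 1.64 FPKM against 20.1 to 26.0 FPKM. None of these 4 genes passed limma between the groups (adjusted p from 0.60 for Malat1 to 0.82 for AY036118). The first principal component of the tested genes, 34.1% of their variance, set control replicate 1 apart.

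With OI, the troponin gene Tnnc1 and the long non-coding RNA H19 had among the largest falls of the genes past the threshold. Tnnc1 (ENSMUSG00000091898, chromosome 14, 31208312 to 31211729, GRCm38), the calcium-binding troponin subunit of slow skeletal and cardiac muscle, went from 126 ± 15.1 FPKM (SD, n = 3) in control to 23.2 ± 1.39 FPKM (SD, n = 3) in OI. Its log2 fold change was -2.39 ± 0.11 (SE), a 5.23-fold fall on the FPKM + 1 scale (limma adjusted p = 0.000188). H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143), an imprinted RNA that is abundant in developing muscle and hosts the microRNA gene Mir675, went from 133 ± 2.95 to 27.4 ± 4.20 FPKM (SD, n = 3 each), a log2 fold change of -2.25 ± 0.11 (limma adjusted p = 0.00023). Over the 1737 genes tested, 48 passed a limma adjusted p of 0.05, of which 20 were higher and 28 lower in OI, and 16 of them changed 2-fold or more on the log2(FPKM + 1) scale. In all 48 the groups did not overlap. Among all tested genes 23.6% showed no overlap, against the 10% that chance gives for 3 against 3.

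**Figure D1:**
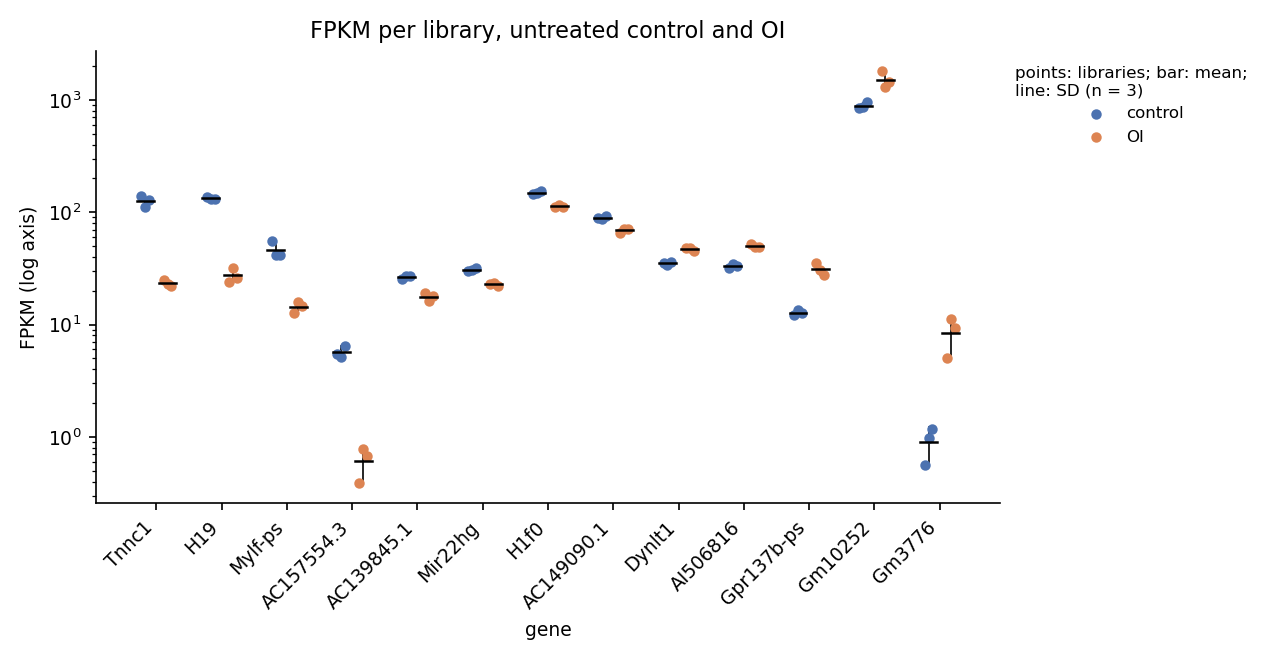
FPKM on a log axis of 13 genes past an adjusted p of 0.05 in the 3 control and 3 OI libraries, where points are libraries, horizontal bars are means and vertical lines are SDs. Tnnc1 falls from a mean of 126 to 23.2 FPKM and H19 from 133 to 27.4 FPKM, and Gm3776 rises from a mean of 0.91 to 8.48 FPKM.

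The naming rule fixed before the data were examined took 6 falls and 2 rises. Besides Tnnc1 and H19, the falls were AC139845.1, a long intergenic RNA on chromosome 15 (26.5 to 17.7 FPKM, log2 fold change -0.56 ± 0.08), Mir22hg, the host transcript of the microRNA gene Mir22 (30.8 to 22.7 FPKM, -0.42 ± 0.07), H1f0, the linker histone H1.0 of non-dividing and differentiated cells (150 to 113 FPKM, -0.40 ± 0.06), and AC149090.1, a protein-coding gene on the unplaced scaffold JH584304.1 (89.6 to 69.2 FPKM, -0.37 ± 0.07). Their limma adjusted p-values lay between 0.0267 and 0.0482. The rises were AI506816, a processed transcript on chromosome 5 (33.2 to 49.9 FPKM, 0.57 ± 0.06, limma adjusted p = 0.0114), and Dynlt1, a dynein light chain (35.2 to 47.1 FPKM, 0.41 ± 0.07, limma adjusted p = 0.0365). The value of Dynlt1 is uncertain, because its transcript matches Dynlt1c at 99.2% identity. H1f0 shares exonic bases with the antisense gene Gm49544, and Mir22hg with Tlcd2. The calls of Mir22hg, H1f0, AC149090.1 and Dynlt1 were lost without any 1 of the 6 libraries (limma adjusted p from 0.0676 to 0.159), that of AC139845.1 without any but OI replicate 1 (up to 0.109), and that of AI506816 without OI replicate 2 (0.0556) or OI replicate 3 (0.0516). Quantile normalization ended the limma calls of H1f0 (log2 fold change -0.18, adjusted p = 0.457), AC149090.1 (-0.13, adjusted p = 0.620) and Mir22hg (-0.40, adjusted p = 0.0536). With trend=FALSE those 3 and Dynlt1 did not pass (limma adjusted p from 0.0549 to 0.0904), nor did AC149090.1 with a pseudocount of 0.1 (0.0504), a pseudocount of 5 (0.059) or median-of-ratios scaling (0.0761).

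Of the 48 called genes 22 share exonic bases with a protein-coding gene, against 750 of all 1737 tested genes. Near-identical to a protein-coding transcript of another gene are 18 of the 48, against 515 of the 1737. Whether the authors' counting used strand is not given in the sources used here, so the values of these genes cannot be separated from those of their partners. Of the 48, 5 shared exonic bases with no other annotated gene, coding or not, and had no such match, namely Tnnc1, Klhl33, AI506816, AC139845.1 and 4933407K13Rik, whose call was lost without any 1 library (limma adjusted p from 0.106 to 0.147), with robust=TRUE (0.0874), with a pseudocount of 0.1 (0.102) or over genes without links (0.0787). AC149090.1 was not assessed for links. The genes in the next 2 paragraphs were chosen after their values were seen.

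Among the falls, AC157554.3 (chromosome 15, 77014093 to 77015898), antisense to exons of the myoglobin gene Mb, went from 5.69 ± 0.70 to 0.61 ± 0.20 FPKM (SD, n = 3 each), a log2 fold change of -2.05 ± 0.13 (limma adjusted p = 0.000775). That value was -0.93 with a pseudocount of 5 and -3.21 on recovered read numbers. Mylf-ps, a pseudogene 99.3% identical to the fast-muscle myosin light chain transcript Myl1, went from 46.2 ± 7.96 to 14.4 ± 1.55 FPKM (SD, n = 3 each; limma adjusted p = 0.00282). Klhl33, a kelch-family gene, went from 4.69 to 1.84 FPKM, a 2.00-fold fall on the FPKM + 1 scale (limma adjusted p = 0.00229). Gm27786 and Gm27483, genes of 70 and 71 bases inside H19 exons on the opposite strand, fell with it by 2.36 and 2.47 on the log2 scale. Antisense genes over the secreted Wnt modulator Sfrp2 (Gm26771, -1.61), the matrix proteoglycan Prelp (Gm15851, -1.89), the complement protease C1s1 (Gm16567, -1.80), the actin-binding protein Tagln (Gm48529, -1.01) and the matricellular protein Ccn2 (Gm15270, -1.16) were lower in OI. So was Gm47302, a microRNA gene in an exon of the collagen gene Col3a1 (551 to 369 FPKM, -0.58). The limma calls at Tagln, Ccn2 and Col3a1 were each lost in 5 of the 6 fits without 1 library, with adjusted p-values of Gm48529, Gm15270 and Gm47302 up to 0.107, 0.147 and 0.157. Gm48529 passed without control replicate 2, and the others without control replicate 1. The call of Gm47302 also ended with quantile normalization (limma adjusted p = 0.348) and trend=FALSE (0.0599), and that of Gm15270 with a pseudocount of 5 (0.0516). With a pseudocount of 5 the log2 fold changes of Klhl33, Gm26771, Gm48529 and Gm15270 were -0.50, -0.99, -0.39 and -0.58. That of Gm48529 was -1.65 with a pseudocount of 0.1 and -1.78 on recovered read numbers.

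**Figure D2:**
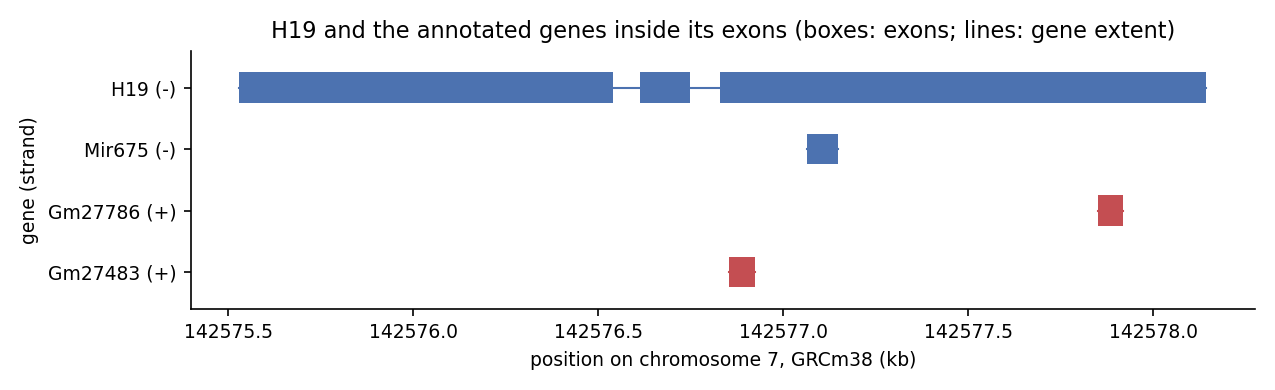
Map of the H19 gene on chromosome 7 in GRCm38, in kilobases, with boxes for annotated exons and lines for gene extents, blue for the minus strand and red for the plus strand. Gm27786 and Gm27483 lie within H19 exons on the opposite strand, and Mir675 on the same strand.

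Among the rises, Gm3776 (chromosome 9, 78257129 to 78269166), 99.5% identical to the glutathione S-transferase transcript Gsta1, went from 0.91 ± 0.32 to 8.48 ± 3.10 FPKM (SD, n = 3 each), a log2 fold change of 2.27 ± 0.28 (limma adjusted p = 0.0129), which was 1.16 with a pseudocount of 5. Gm10252, which overlaps exons of the ferritin light chain gene Ftl1 on the opposite strand, went from 880 ± 60.0 to 1506 ± 257 FPKM (0.76 ± 0.13, limma adjusted p = 0.0423), and Gm47428, antisense to Ftl1-ps1, from 19.7 to 34.9 FPKM (0.80, limma adjusted p = 0.0186). Gm6644, a pseudogene 99.7% identical to the aldose reductase transcript Akr1b3, went from 2.58 to 5.82 FPKM (0.93, limma adjusted p = 0.00718), and Gm37784, 98.9% identical to part of the sterol-sensing regulator transcript Insig1, from 4.97 to 11.5 FPKM (1.07, limma adjusted p = 0.0372). Gpr137b-ps, 97.4% identical to the lysosomal membrane protein transcript Gpr137b, went from 12.8 ± 0.64 to 31.1 ± 3.69 FPKM (SD, n = 3 each; limma adjusted p = 0.00232). Further rises, Gm21698, Gm1979, Gm21663, Gm21680 and Gm21671, form a family on chromosome 5 between 25935791 and 26004798. Their best matches were transcripts of other genes, 5031410I06Rik, Gm10220 and Gm7347, at 94.7% to 99.7% identity. Their values therefore cannot be taken as separate signals. Their log2 fold changes ran from 0.60 to 0.86. With a pseudocount of 5 these ran from 0.22 to 0.56, and that of Gm6644 was 0.51. Gm21671 was at 1.00 with a pseudocount of 0.1 and 1.10 on recovered read numbers. The limma calls of Gm21680 and Gm21671 were lost without any 1 library (adjusted p up to 0.109 and 0.150), that of Gm21663 without any but OI replicate 1 (up to 0.109), that of Gm1979 without control replicate 2, OI replicate 2 or OI replicate 3 (up to 0.0685), and that of Gm21698 without OI replicate 2 or 3 (up to 0.0618). The limma call of Gm3776 was lost without control replicate 2 (adjusted p = 0.0645), OI replicate 2 (0.0556) or OI replicate 3 (0.0652). That of Gm10252 was lost without any 1 library (up to 0.157), and those of Gm37784 and Gm47428 without any but control replicate 3 (up to 0.141 and 0.0789). The call of Gm10252 also ended with quantile normalization (limma adjusted p = 0.408) and trend=FALSE (0.0549), that of Gm21671 with a pseudocount of 0.1 (0.057), and that of Gm37784 on recovered read numbers (limma voom adjusted p = 0.0766).

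Of the 30 gene lists fixed beforehand, none had 3 tested members, so the planned set test could not be made. Of their members 9 were among the genes analysed, and the 7 tested were described singly. Tnnc1 was the only tested sarcomere gene, so adjustment over the list alone leaves its unadjusted limma p of 3.09e-07 and adds no test. Hspa1b, a heat shock protein, was at 40.4 ± 0.30 FPKM in control and 46.4 ± 0.35 FPKM in OI (SD, n = 3 each), with a limma adjusted p of 0.156 over all genes and 0.0271 adjusted over the list alone. Hmgcs1, an enzyme of cholesterol synthesis (71.6 to 88.2 FPKM), and Ccnd2, cyclin D2 (24.5 to 28.3 FPKM), had limma adjusted p-values of 0.177 and 0.228 over all genes. Each was the only tested member of its list, so over the list alone their limma p-values stayed unadjusted, at 0.0168 and 0.0256. For Hspa1a, Sdhd and Cox5a the limma p-values adjusted over all genes and over the list alone were above 0.2.

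To use the lists, tested genes were linked to list members after the data were seen. A link was the member itself, a gene sharing exonic bases with it, or a gene whose best near-identical match was the member. This gave 15 lists with 3 or more genes. The 7 genes linked to NRF2 targets were all higher in OI, with a median log2 fold change of 0.49. Gm3776 and Gm10252 passed the test singly, and the genes linked to Gclm, Gstm1, Me1 and Prdx1 did not, with values from 0.22 to 0.65 (limma camera adjusted p = 0.000441, and adjusted p = 0.107 with an estimated correlation). The median was 0.26 without OI replicate 1 and 0.29, with 6 of 7 higher, without control replicate 2, and 0.29 with a pseudocount of 5. Of the 8 genes linked to the 6 muscle lists together 7 were lower, with a median of -0.43. Of these, 3 passed the test singly, Tnnc1, AC157554.3 and Mylf-ps (limma camera adjusted p = 0.000213, and adjusted p = 0.107 with an estimated correlation). The genes linked to Atp2a2, Rapsn, Vcam1, Mef2d and Nphs1 did not (limma adjusted p from 0.319 to 0.920). Their log2 fold changes ran from -0.48 to 0.08, and for each of them the groups overlapped. The gene linked to Nphs1 is the ribosomal protein pseudogene Rps12-ps4. The median of the muscle-linked genes was -0.66 with a pseudocount of 0.1, -0.17 with a pseudocount of 5, -0.74 on recovered read numbers and -1.61 over the 5 genes left by a filter at 5 FPKM. With rescaling to a common sum, which moved the median of all genes to 0.53, it was -0.14, with 3 of 8 higher, and that of NRF2 targets was 1.16.

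Genes linked to cholesterol synthesis (6 of 7 higher, median 0.30) had a limma camera adjusted p of 0.00934, and an adjusted p of 0.451 with an estimated correlation. Those linked to heat shock response (6 of 7 higher, 0.15) had a limma camera adjusted p of 0.0105, and an adjusted p of 0.211 with an estimated correlation. In both lists several genes share a member, so their genes are not independent. For cholesterol synthesis, Gm5873 and Gm3571 match Fdps, and Gm48342 overlaps Hmgcs1, itself in the list. For heat shock response, Gm8355, Gm6210 and Gm15459 match Hspa8, and Gm20481 overlaps Hspa1a, itself in the list. The 3 genes linked to cell cycle exit were Ccnd2, its overlapping antisense gene Gm43126 and E230016M11Rik, a gene over the stress gene Gadd45a. All 3 had higher means in OI, but E230016M11Rik was at 0.31, 0.34 and 8.28 FPKM in control replicates 1 to 3 and between 6.24 and 8.35 FPKM in OI, so that control replicate 3 lay at the OI level. The list had a median of 0.20 (limma camera adjusted p = 0.0306, and adjusted p = 0.267 with an estimated correlation). It holds D-type cyclins such as Ccnd2 beside cell cycle inhibitors, so its direction does not tell whether more or fewer cells left the cycle. Those linked to BMP and TGF-beta responsive genes (3 of 3 lower, -0.45) and extracellular matrix (3 of 3 lower, -0.39) both had a limma camera adjusted p of 0.0306, and an adjusted p of 0.211 with an estimated correlation. Of those linked to glycolysis, mostly Gapdh pseudogenes, 10 of 15 were lower (-0.18, limma camera adjusted p = 0.0487, and adjusted p = 0.451 with an estimated correlation). With 1 value per list member, glycolysis had 6 values, a median of -0.12 and a limma camera adjusted p of 0.605.

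Leaving out 1 library ended 4 of these calls. The limma camera adjusted p rose to between 0.053 and 0.104 for BMP and TGF-beta responsive genes (without control replicate 2, OI replicate 1 or OI replicate 2), between 0.0609 and 0.108 for cell cycle exit (control replicate 1, OI replicate 1 or OI replicate 2), between 0.0562 and 0.104 for extracellular matrix (control replicate 2, control replicate 3 or OI replicate 1) and between 0.0847 and 0.262 for glycolysis (control replicate 1, 2 or 3, or OI replicate 3). The glycolysis median was -0.052 without control replicate 1 and -0.059 without OI replicate 3, that of cholesterol synthesis 0.20 without control replicate 1, and that of heat shock response 0.067 without OI replicate 1. Quantile normalization ended the limma camera calls of cell cycle exit, extracellular matrix and glycolysis (adjusted p = 0.0636, 0.110 and 0.543), and the filter at 5 FPKM that of cell cycle exit (0.0551). With limma's fry, cholesterol synthesis, cell cycle exit and glycolysis did not pass (adjusted p = 0.134, 0.0572 and 0.106). With rescaling to a common sum, cholesterol synthesis, heat shock response, extracellular matrix and glycolysis did not pass limma camera (adjusted p = 0.122, 0.485, 0.485 and 0.771). Their medians there were 0.89, 0.76, 0.0084 and 0.40, and those of cell cycle exit and BMP and TGF-beta responsive genes 0.79 and 0.075. The glycolysis call also ended with a pseudocount of 5 or trend=FALSE (limma camera adjusted p = 0.058 and 0.0725). The glycolysis median was -0.076 with a pseudocount of 5 and -0.30 with the filter at 5 FPKM, and that of extracellular matrix -0.15 with a pseudocount of 5 and -0.59 on recovered read numbers. The other 7 lists did not pass with either correlation, among them genes linked to mitochondrially encoded mRNAs (8 genes, median 0.00, limma camera adjusted p = 0.714) and to integrated stress response (3 genes, 0.06, limma camera adjusted p = 0.703), ER stress (3, -0.20, 0.319), nuclear-encoded oxidative phosphorylation (4, -0.13, 0.426), muscle atrophy and proteolysis (4, 0.08, 0.714), reserve cell and satellite cell (3, -0.03, 0.714) and the TCA cycle (3, -0.02, 0.973). The genes linked to ER stress all link to 1 member, Hsp90b1. Those linked to integrated stress response are Tmem189 and Nup62, protein-coding genes that overlap Cebpb and Atf5, and a pseudogene matching Phgdh. Whether these 2 responses changed cannot be told from such genes.

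**Figure D3:**
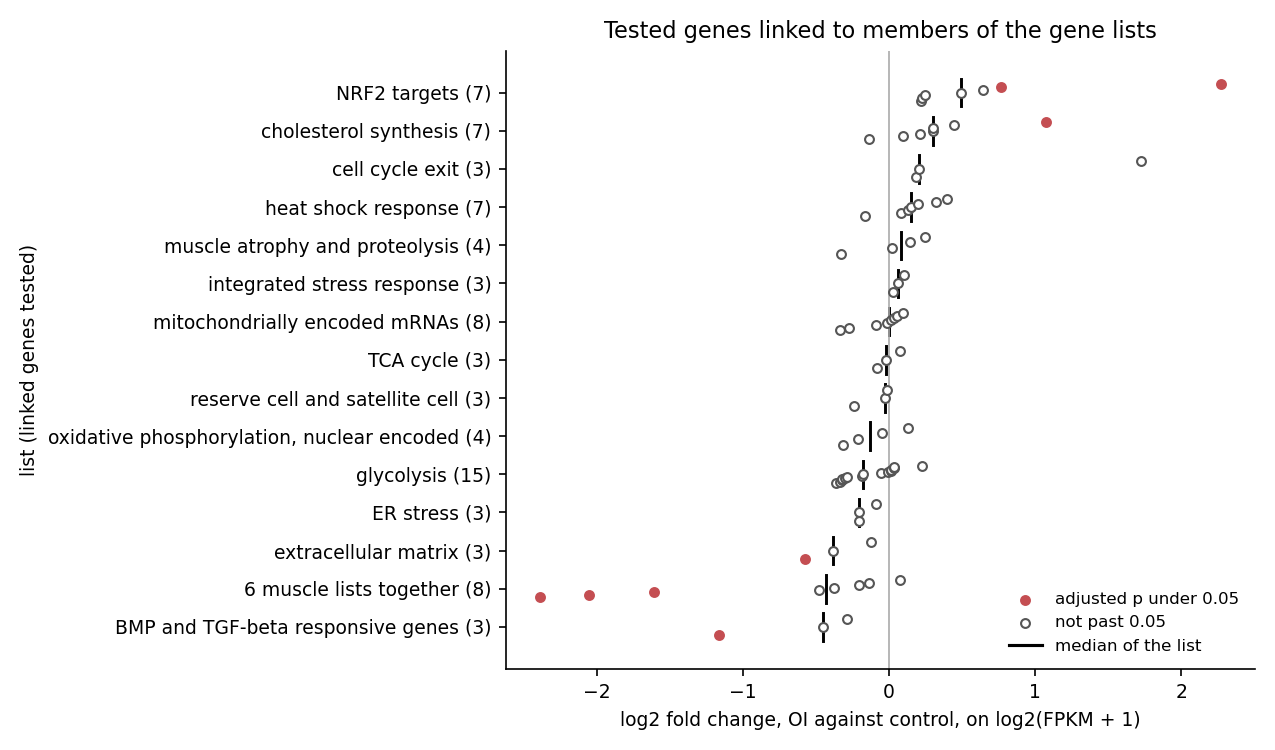
Log2 fold change of OI against control on log2(FPKM + 1) for the tested genes linked to each of the 15 lists, with the number of genes in parentheses; each point is a gene, filled where its adjusted p is under 0.05, and the vertical bar is the list's median. All 7 NRF2-linked genes lie above 0, and 7 of the 8 muscle-linked genes lie below 0, with Tnnc1 at -2.39.

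The number of genes past the threshold was lower without any 1 library, in fits that also had fewer samples. Without control replicate 1, 2 or 3 it was 24, 19 or 27, and without OI replicate 1, 2 or 3 it was 24, 15 or 16, while 13 of the 48 passed in each of these 6 fits, namely Tnnc1, H19, Gm27786, Gm27483, AC157554.3, Mylf-ps, Klhl33, Gm16567, Gm26771, Gm15851, Gm11747, Gpr137b-ps and Gm6644. Without a filter on low values 13 of the 48 passed limma, and with rescaling to a common sum 1 did.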

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

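The linked lists, their test with 1 value per list member, the fit on recovered read numbers and the fit on genes without links were chosen after seeing the data; the other alternatives were fixed beforehand. All 48 called genes kept their direction in every alternative that tested them except rescaling to a common sum over the genes analysed, and Tnnc1 (log2 fold change -2.48 to -2.21) and H19 (-2.36 to -2.08) stayed past the threshold in every other alternative that tested them (the fit on genes without links left H19 out). That rescaling moved the median of all genes to 0.53, because control replicate 1, rich in rRNA-derived RNA, has an FPKM sum of 189789 against 51797 to 56771 in the others. It gave 7 genes, of which 1 was among the 48, 7 higher and 0 lower, 7 of them changed 2-fold or more (limma, 63 genes at an unadjusted p under 0.05), and 4 linked lists, and turned the direction of H1f0 (0.18), Mir22hg (0.15), Gm47302 (0.0084) and AC149090.1 (0.21), and of the lists linked to BMP and TGF-beta responsive genes (0.075), extracellular matrix (0.0084) and glycolysis (0.40). Relative to that median all of these lay below 0. Without a filter, 10948 genes were tested and 14 passed (3 higher, 11 lower), with 13 of the 48 among them. Genes without any link numbered 381, of which 4 passed (1 higher, 3 lower, 2 changed 2-fold or more). A pseudocount of 5 gave 9 genes changed 2-fold or more and the fit on recovered read numbers 32 among 62 called of 3056 tested, 45 of them shared with the 48. A larger pseudocount shrinks low genes by construction, and 24 of the 48 log2 fold changes were smaller by over 1.5 times with it. The fit on read numbers changed the scale, the filter and the test together, so the cause was not tested.

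Leaving out 1 library left 15 to 27 genes (2 to 11 higher, 13 to 16 lower, 12 to 15 changed 2-fold or more) and 5 to 7 linked lists, with fewer samples per fit. The linked lists past the threshold numbered 5 with the filter at 5 FPKM, where only 9 lists could be tested (neither BMP and TGF-beta responsive genes nor extracellular matrix among them), 5 with quantile normalization, 5 with fry, 6 of 13 with 1 value per list member (cell cycle exit could not be tested) and 0 with an estimated correlation, where 2 lists, NRF2 targets and the muscle lists, had an unadjusted p under 0.05 (limma camera); those 2 passed in every other alternative. The cause was not tested.

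With the replicate number as a block, 17 genes passed (3 higher, 14 lower), 15 of them among the 48, and 7 linked lists, without glycolysis (limma camera adjusted p = 0.0584). The labels do not say whether the numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at 0.05, 0.14 and -0.08. Control replicate 2 correlated best with its own number, and control replicates 1 and 3 did not. Control replicate 1 was at 0.047 with OI replicate 1 and 0.052 with OI replicate 3. With 3 libraries per group these correlations cannot decide whether the samples are paired.

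Depth limits genes of few reads: AC157554.3 rested on recovered read numbers, rounded, of 85, 100 and 124 in control replicates 1 to 3 and of 8, 18 and 11 in OI replicates 1 to 3.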

Other observations

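The genes in this part, and all its tests except the 2 on control replicate 1, the splits for linked lists and the count of targets tested beside their linked genes, were chosen after the results were seen. Ugt1a7c, a glucuronosyltransferase, did not pass the test and was at 0.77 ± 0.39 FPKM in control and 3.06 ± 1.32 FPKM in OI (SD, n = 3 each; limma adjusted p = 0.11), and Ugt1a6b, which shares exons with it and did not pass either, was at 9.85 ± 8.03 and 20.9 ± 3.02 FPKM (limma adjusted p = 0.40). The antisense gene 0610031O16Rik over the alcohol dehydrogenase gene Adh7 went from 0.39 to 1.27 FPKM (limma adjusted p = 0.0267), and its call was lost without any 1 of the 6 libraries (limma adjusted p from 0.0717 to 0.116) and with a pseudocount of 0.1 (0.0552). On recovered read numbers, limma voom called 17 genes that the FPKM fit did not, 7 of which that fit had not tested. Among the 17 were Myl6, a non-muscle and smooth muscle myosin light chain (log2 fold change -0.33, adjusted p = 0.0384), the complement gene Cfb (-0.91, adjusted p = 0.0291) and Gm15459, a pseudogene of the heat shock protein transcript Hspa8 (0.32, adjusted p = 0.0147).

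With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 48 genes and the highest of the others 2. It gave 16 genes changed 2-fold or more against 2, and 8 linked lists against 1. In each case 1 of the 10 splits, the real one, gave as many. Each of the other splits mixes libraries of both groups, so a difference between the groups adds to the spread there and lowers the counts. Those counts are therefore not the level that chance alone would give.

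Control replicate 1 carried far more rRNA-derived and 7SL RNA than the other libraries. If these reads had lowered the FPKM of its other genes, the tested genes would lie below those of the other controls. Their median log2 difference was 0.0017, so the tested genes as a whole did not lie lower. That cannot exclude a lowering of the genes not analysed, since only 310 of the 1737 tested genes were protein-coding. A wider excess of non-coding RNA would also hide a lowering. In control replicate 1, 1893 of the genes analysed reached 1 FPKM, against 1643 to 1717 in the other libraries. Without this library 24 genes passed limma, 20 of them among the 48, so 28 of the 48 calls were lost; without any 1 library 15 to 27 genes passed. The log2 fold changes of the 48 without it were 0.99 times those with it (median), which does not decide whether the changes rest on it, since the 48 were chosen with it. The source of the excess RNA stays open, and no biological explanation was tested, since the design gives none within a group.

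Non-coding genes over exons of protein-coding genes made up many of the calls. A candidate explanation is that reads of one gene are also counted to its partner on the opposite strand. Over 49 opposite-strand pairs of tested genes, leaving out those of H19 and the rRNA-derived genes, log2 fold changes correlated across pairs with Spearman's rho = 0.65 and Pearson's r = 0.68 (permutation p = 1e-05 for rho, the smallest 100000 permutations can give; pairs of genes are not independent replicates). This is what such counting would give, and antisense RNAs that change with their partners would give it too. Calls were 20 of 600 among non-coding genes that share exonic bases with a protein-coding gene and 15 of 820 among the others (two-sided Fisher's exact p = 0.083), which leaves open whether overlap goes with being called.

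The 7 genes linked to NRF2 targets had higher means in OI, but only Gm3776 and Gm10252 passed the test singly, and a hypothesis is that NRF2 target transcripts are higher as a set. The groups overlapped for Gm6061, linked to Gclm (10.6 to 60.7 FPKM in control and 30.2 to 78.7 FPKM in OI, limma adjusted p = 0.675). They also overlapped for Gm7329 (6.82 to 9.05 and 7.61 to 12.7 FPKM) and Gm7049 (2.24 to 3.68 and 3.51 to 3.73 FPKM), both linked to Me1. So they did for Gstm2-ps1, linked to Gstm1 (3.29 to 4.92 and 4.74 to 6.93 FPKM). No overlap was seen for Gm3776, Gm10252 and Gm21399, the last linked to Prdx1. The camera p was 5.88e-05 with the preset and 0.0143 with an estimated correlation, the latter 0.107 after adjustment over 15 lists. Whether the linked pseudogenes and copies changed themselves or took reads from the targets cannot be told apart, since 0 of the linked genes have their target among the genes tested.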
